A study of Musa acuminata subsp. malaccensis with 4 samples.

How the data were processed

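Messenger RNA was measured in banana seedlings (Musa acuminata subsp. malaccensis) grown in sand and fed a nutrient solution with 136 mg/L or 0 mg/L phosphate for 60 days, per the labels' protocols. The aboveground part and the root were sequenced from each treatment, which gives 4 libraries with 1 library in each group. The number of seedlings per library is not given in the sources used here. Per the labels' protocols, poly(A) RNA was fragmented, copied with random primers, amplified by PCR and sequenced on an Illumina instrument. The aligner, the counting tool, the genome build, the statistical test and the thresholds are not given in the sources used here.

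The values came as 1 table per tissue. Per the file headers, each row holds a gene's length, its estimated count in both libraries, its FPKM (fragments scaled to gene length and library total) in both libraries and the log2 ratio of the FPKM, no phosphate over phosphate. Each row also holds a p-value and an FDR (false discovery rate) between the 2 libraries, a best protein match and pathway terms, per the file headers. The authors' deposited tables were found to hold only genes with an absolute log2 ratio of at least 1, and the largest FDR was 0.000983 aboveground and 0.000994 in the root. Every gene in the tables is therefore one the authors called, and genes that did not differ were not analysed here. The authors replaced an FPKM of 0 by 0.001 in these deposited columns, so their log2 ratios of genes with no count in 1 library have no fixed size. The estimated counts in the deposited columns were whole numbers in 61.6% to 69.3% of genes per library. They carry decimals in the others, and were used as deposited without rounding, since no count model was fitted. The tables carry no coordinates, so no genomic positions are given. Gene identifiers and descriptions are those of the tables. A RefSeq gene table of another assembly matched the protein accessions of 1448 of 1862 aboveground genes and 5720 of 7254 root genes that had one, and it was not used further because it gives no product names.

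The total of each library was recovered from the tables, because FPKM is the count divided by the total and by the length less a constant. Genes with at least 200 counts and at least 600 bases entered this fit. It gave totals of 4306586 and 4340636 fragments for the aboveground libraries with and without phosphate, and 4553436 and 3920566 for the root libraries. The median deviation of single genes from these fits was between 0.00320% and 0.118%. The tables' genes took 7.92% and 11.9% of the aboveground fragments and 38.8% and 37.4% of the root fragments. Folds given here were computed from the estimated counts divided by these totals. Their 95% intervals are exact (Clopper-Pearson) intervals of the share of a gene's fragments in 1 of the 2 libraries. Intervals cover counting error only, since PCR copies are not independent molecules and no replicate was sequenced. Floors allow for counting error only in the library with no count. A gene with no count in 1 library is given as at least N-fold, with 3 counts in that library as the floor and the other count taken as exact. The exact 95% lower bounds of such genes are smaller and stand beside the folds. Among genes with at least 50 counts in both libraries, the log2 ratio from counts lay within 0.1 of the authors' deposited log2 ratio for 99.5% of 873 aboveground genes and 99.6% of 3198 root genes. The largest differences were 0.19 and 0.51.

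With 1 library per group the treatment cannot be tested within a tissue. A fit across both tissues, which would take the difference between tissues as error, was not made, and no p-value across genes was computed. The authors' FDR compares 2 libraries, not 2 treatments. Genes were counted by direction in each table and across both tables. The 23 gene lists were defined by words in the descriptions, and a list with at least 3 listed members was described by its median of the authors' deposited log2 ratios. Its median was placed among 10000 random lists of the same size from the same table, matched on mean FPKM in 10 bins. These percentiles describe the libraries and hold only within genes the authors called. The gene lists, the matching, the rule for naming genes and the alternatives, apart from those said to be added, were fixed before the data were examined. Random lists of non-members matched on gene length were added after the tables had been seen.

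Named genes were chosen by a rule among genes with at least 50 counts in the higher library. It takes the 5 largest and 5 smallest log2 ratios per tissue, the 2 members with the largest absolute log2 ratio in each list with at least 3 members, and the 3 genes of the same and the 3 of opposite direction with the largest smaller ratio across tissues. Genes without an informative description were passed over. The rule took 54 genes per tissue, and part of them are named in the text. Genes named outside the rule are said to be chosen after their values were seen. Some list patterns also took members that the list's name does not cover. These were looked for in the phosphate transporter, organic acid and housekeeping lists only, and are stated beside their counts. Other lists may hold such members too.

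The alternatives were a stricter ratio, a stricter FDR, a count minimum, a pseudocount of 1 on the FPKM, a shift by the median of the housekeeping list, counting intervals beyond 2-fold, other list summaries, and scaling to the tables' own totals. Since no gene within 2-fold is listed, unchanged housekeeping genes could not enter that shift, so it shows how values move but does not measure an error of scaling. The calculations were tested on simulated counts with 200 changed genes per table. The 95% intervals covered the true ratio for 96.7% of unchanged genes, 92.0% of genes changed 2-fold and 96.0% of genes changed 4-fold in the aboveground simulation of 1900 genes. They did so for 95.8%, 98.1% and 94.8% in the root simulation of 7398 genes. Of 100 random lists with no planted change, 1 aboveground and 5 in the root fell outside the central 95%, and a planted list reached percentile 100 in both. The simulated genes were not selected on ratio or FDR and carried no length trend or correlated families. These shares therefore need not hold for the listed and named genes or for the percentiles of the real lists. The work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.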

Results

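The transcriptomes of banana seedlings supplied with phosphate or deprived of it were compared in the aboveground part and in the root. Each of the 4 groups was 1 library, so no difference below has a replicate check. The aboveground libraries held 4306586 fragments with phosphate and 4340636 without, and the root libraries 4553436 and 3920566. The authors' deposited table listed 1900 genes aboveground and 7398 genes in the root. Higher and lower below mean higher or lower in the library without phosphate than in the library with phosphate of the same tissue.

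The aboveground comparison asked which transcripts differed in shoots after 60 days without phosphate. Most listed genes of phosphate uptake, phosphate sensing, phosphate release and membrane lipid exchange were higher without phosphate. Of the listed genes, 1064 were higher and 836 lower, and 394 were higher and 187 lower by 4-fold or more. Ma03_g26260 is described as inorganic phosphate transporter 1-11-like, a member of the family that carries phosphate across the plasma membrane. It had no count with phosphate and 2493 counts without it, at least 824-fold higher (95% counting interval from 670). The SPX gene Ma01_g15270 (SPX domain-containing protein 5-like) went from 2 to 2442 counts, 1211-fold higher (335 to 10009).

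Of 9 listed aboveground members of the phosphate transporter list, 8 were higher and 1 lower, with a median log2 ratio of 4.10, and 2.77 after the housekeeping shift given below. The list pattern also took 3 carriers whose descriptions do not name inorganic phosphate. These were Ma11_g04090 and Ma08_g10940 (putative glycerol-3-phosphate transporter 1), both higher, and Ma01_g02090 (probable anion transporter 2, chloroplastic), the lower member, all named after their values were seen. Without these 3, a choice made after the values were seen, the median was 6.18. Ma01_g01890 (probable inorganic phosphate transporter 1-8) had 2 counts with phosphate and 532 without, 264-fold higher (72.7 to 2185). SPX proteins bind inositol pyrophosphates and report the phosphate state of the cell, and 8 of 10 members of the SPX and phosphate signalling list were higher (median 2.5, and 1.17 after the shift). Ma04_g30530 (SPX domain-containing protein 3-like) was 125-fold higher (77.7 to 215). The 2 lower members, Ma11_g06080 (protein PHR1-LIKE 1-like) and Ma05_g10190 (SPX domain-containing membrane protein OsI_17046-like), were named after their values were seen.

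All 12 listed aboveground acid phosphatases and ribonucleases, enzymes that free phosphate from organic molecules and RNA, were higher (median 3.25, and 1.91 after the shift). Ma06_g25400 (probable purple acid phosphatase 20) had no count with phosphate and 55 without, at least 18.2-fold higher (from 14.3). Ma01_g01850 (purple acid phosphatase 23) had 1 and 54 counts, 53.6-fold higher (9.22 to 2155). In the membrane lipid remodelling list 8 genes were higher and 3 lower (median 3.54, and 2.20 after the shift). Ma04_g12810, a probable monogalactosyldiacylglycerol synthase 3, which makes galactolipids that can replace phospholipids, went from 20 to 1842 counts, 91.4-fold higher (59.0 to 150). Ma10_g19370 (phosphatidate phosphatase PAH2-like) had no count with phosphate and 107 without, at least 35.5-fold higher (from 28.3). The 3 lower members were Ma02_g01740 (phospholipase D p1-like), Ma08_g09380 (non-specific phospholipase C2) and Ma11_g10840 (phosphoethanolamine N-methyltransferase 1-like), named after their values were seen. Each of these 4 list medians lay at or above percentile 99.6 of random lists, matched on expression or on length.

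**Figure D1:**
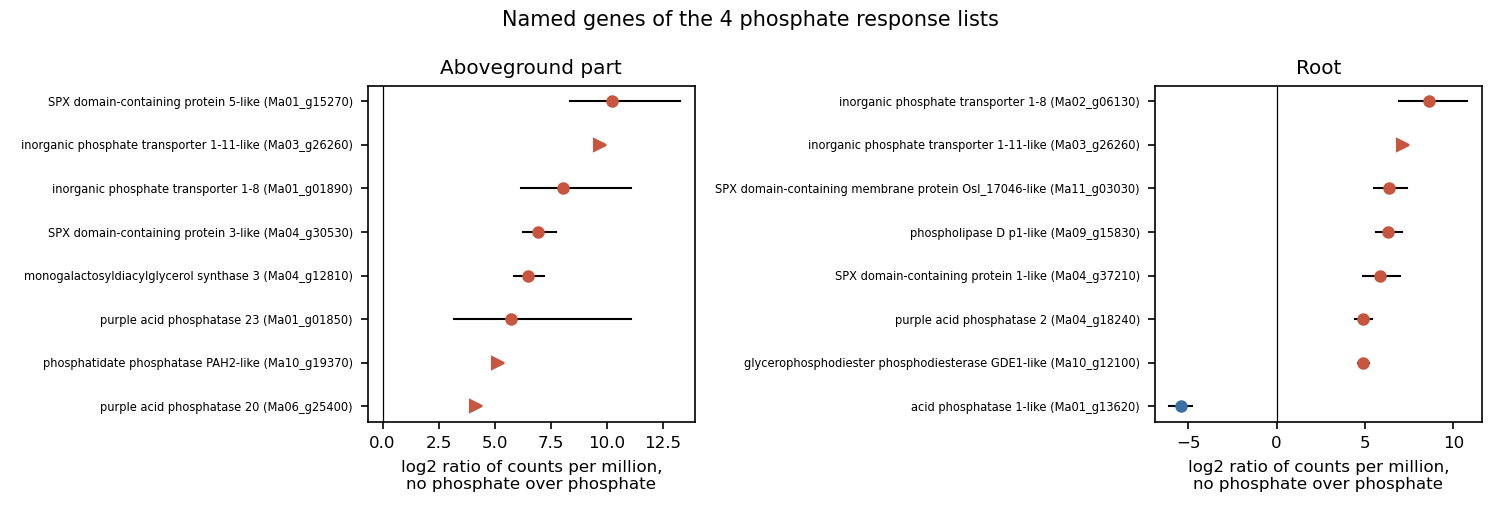
Log2 ratio of counts scaled to library totals, no phosphate over phosphate, of the named genes of the 4 phosphate response lists in the aboveground part and the root, 1 library per group. Circles are ratios with 95% counting intervals and triangles are lower bounds of genes with no count with phosphate; acid phosphatase 1-like (Ma01_g13620) in the root is the 1 gene plotted below 0.

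Phosphoenolpyruvate carboxylase, which makes oxaloacetate and frees phosphate, was higher aboveground. Ma04_g08080 (phosphoenolpyruvate carboxylase 2) went from 249 to 4483 counts, 17.9-fold higher (15.7 to 20.4), and Ma02_g14160, a kinase of this enzyme, was 9.71-fold higher (6.15 to 16.8). In the organic acid and glycolytic bypass list, 8 members were higher and 5 lower (median 2.05, and 0.72 after the shift). The lower 5, named after their values were seen, were Ma01_g18100 (malate dehydrogenase [NADP]), Ma11_g10170 and Ma10_g26390 (aluminum-activated malate transporter 9-like), Ma04_g27480 (phosphoenolpyruvate carboxykinase) and Ma10_g21340 (NADP-dependent malic enzyme).

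Defence and cell wall genes were also mostly higher aboveground. Of the pathogenesis related list 36 genes were higher and 4 lower (median 1.89, and 0.56 after the shift), among them Ma02_g15080 (pathogenesis-related protein 1-like), 10.9-fold higher (7.10 to 18.3), and Ma05_g29060 (putative germin-like protein 2-1), 15-fold higher (6.58 to 41.6). Of the cell wall modification list 22 were higher and 5 lower (median 1.85, and 0.52 after the shift), with Ma03_g05090, a probable xyloglucan endotransglucosylase, 5.73-fold higher (4.18 to 8.08). Ethylene genes stood at 12 higher and 3 lower (median 1.95, and 0.62 after the shift), with Ma11_g03090 (ethylene-responsive transcription factor ERF024-like) 19.2-fold higher (7.97 to 60.6). WRKY, MYB, NAC and bHLH transcription factors stood at 45 higher and 11 lower (median 1.55, and 0.22 after the shift). The sulfate transporter Ma10_g27220 was 38.2-fold higher (14.6 to 142) in a sulfate and potassium transport list with 4 members higher and 8 lower (median -1.12, -2.45 after the shift, and 2.17 among members at 4-fold or more). The cyclin-dependent kinase inhibitor Ma04_g33070 was 26.3-fold higher (14.5 to 53.3), in a histone and cell cycle list of 15 higher and 4 lower (median 1.34, and 0.0029 after the shift). Among length-matched random lists, the medians lay at percentiles 99.8 for pathogenesis related, 99.97 for cell wall modification and 97.8 for ethylene genes. They lay at 91.6 for the transcription factors, 34.5 for sulfate and potassium transport and 42.0 for histones and cell cycle.

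Lower transcripts aboveground included flavonoid and nitrate genes. The chalcone synthase Ma06_g12370, the entry enzyme of flavonoid synthesis, was 27.1-fold lower (7.04 to 226) and the flavonol sulfotransferase-like gene Ma04_g14470 was 29.7-fold lower (7.87 to 251). Their list, phenylpropanoid and flavonoid, held 16 higher and 10 lower members. Of nitrogen uptake and assimilation genes 7 were higher and 11 lower (median -1.16, and -2.49 after the shift), with Ma04_g37230 (protein NRT1/ PTR FAMILY 6.2-like) 18.3-fold lower (7.41 to 56.6) and the nitrate transporter Ma08_g13030 8.49-fold higher (5.11 to 14.9). Auxin genes stood at 3 higher and 10 lower (median -1.17, and -2.50 after the shift), sugar transport and starch genes at 3 and 7 (-1.24 and -2.57), aquaporins at 1 and 4 (-1.82 and -3.16) and metal transport genes at 2 and 3 (-1.19 and -2.52). Among length-matched random lists, the medians lay at percentiles 3.6 for nitrogen, 16.9 for auxin and 7.06 for sugar transport and starch genes. They lay at 0.67 for aquaporins, 22.4 for metal transport and 50.3 for phenylpropanoid genes. At 4-fold or more the auxin list held only 1 gene, Ma04_g17130 (log2 ratio 2.90), and the metal transport list only 1, Ma06_g01180 (2.61), both higher. The amine oxidase Ma01_g13020 had 82 counts with phosphate and none without, at least 27.5-fold lower (from 21.9). Ma02_g13560 (cyclin-dependent kinases regulatory subunit 1-like) went from 50 counts to none, but Ma02_g13600, a copy with the same description and length, had the opposite call, and the log2 ratio of the summed counts was -0.80.

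More members were higher than lower aboveground among peroxidases and redox enzymes (20 higher, 5 lower, median 1.19), heat shock proteins and chaperones (14 and 7, median 1.11), photosynthesis genes (3 and 0, median 1.22) and ribosomal proteins (7 and 1, median 1.21). Their medians lay at percentiles 8.54, 26.8, 53.5 and 25.4 of length-matched random lists. The photosynthesis median is the value of Ma04_g38200, a ferredoxin--NADP reductase described as an embryo isozyme. Another of the 3 is Ma06_g24830, described as a RuBisCO large chain, so this list does not stand for photosynthesis transcripts at large. With log2 ratios shifted by 1.33, the median of the 5 listed housekeeping genes (3 higher, 2 lower), the medians of these 4 lists and that of the phenylpropanoid list turned negative, and 25.9% of the genes still past 2-fold were higher, in place of 56.0%. No unlisted gene can enter, so this shift takes out higher genes only, and the share falls by construction. The 5 genes ranged from a log2 ratio of -2.25 to 1.58, the latter Ma06_g03680 (NADP-dependent glyceraldehyde-3-phosphate dehydrogenase). With any 1 of the 3 higher ones left out, the median would fall between a higher and a lower gene. Every aboveground value after the shift therefore hangs on single genes.

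The root comparison asked the same of roots. Phosphate transporter and SPX genes were again mostly higher without phosphate, while nearly all listed ribosomal protein genes were lower. Of the listed root genes 3290 were higher and 4108 lower, and 947 were higher and 1911 lower by 4-fold or more. The transporter Ma03_g26260 again had no count with phosphate and had 373 without, at least 144-fold higher (from 117). Of 353 listed ribosomal protein genes, 352 were lower and 1 higher, and together they took 3.62% of the root fragments with phosphate and 0.873% without.

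All 11 listed root members of the SPX and phosphate signalling list were higher (median 3.86, and 5.68 after the shift given below). Ma11_g03030 (SPX domain-containing membrane protein OsI_17046-like) was 82.4-fold higher (45.8 to 166) and Ma04_g37210 (SPX domain-containing protein 1-like) 56.6-fold higher (29.5 to 124). Of 17 root members of the phosphate transporter list, 15 were higher and 2 lower (median 1.98, and 3.79 after the shift), with Ma02_g06130 (probable inorganic phosphate transporter 1-8) 388-fold higher (123 to 1751). The 2 lower members were Ma10_g01160 (probable anion transporter 6) and Ma09_g00850 (molybdate-anion transporter-like), named after their values were seen. They are among 5 members taken by the list pattern whose descriptions do not name inorganic phosphate. Without these 5, a choice made after the values were seen, the median was 2.05. Of the membrane lipid remodelling list 16 were higher and 3 lower (median 1.46, percentile 99.4 of expression-matched and 83.5 of length-matched random lists, and 3.27 after the shift). Ma09_g15830 (phospholipase D p1-like) was 80.3-fold higher (49.9 to 138), and Ma10_g12100, a glycerophosphodiester phosphodiesterase that acts on deacylated phospholipids, 29.9-fold higher (24.4 to 37.0). The 3 lower ones, Ma08_g26450, Ma07_g18790 and Ma11_g10840, were named after their values were seen.

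Root acid phosphatases and ribonucleases went both ways, with 8 higher and 10 lower and a median of -1.16, which was 0.66 after the shift and 2.41 among members at 4-fold or more. Ma04_g18240 (purple acid phosphatase 2) was 29.9-fold higher (21.6 to 42.1) and Ma01_g13620 (acid phosphatase 1-like) 42.2-fold lower (28.0 to 66.8). Several of the lower members were ribonucleases. Ma04_g08930 (ribonuclease 3-like), chosen after its values were seen, was 10.9-fold lower (9.76 to 12.2). Of the organic acid and glycolytic bypass list 7 were higher and 16 lower (median -1.22, 0.60 after the shift, and 0.16 among members at 4-fold or more). All 5 members outside the list's name, ATP-citrate synthase and 3-isopropylmalate dehydrogenase genes, were lower, among them Ma08_g06070, 29.1-fold lower (20.2 to 43.3). The kinase of phosphoenolpyruvate carboxylase Ma04_g18750 was 17.9-fold higher (11.0 to 31.2).

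**Figure D2:**
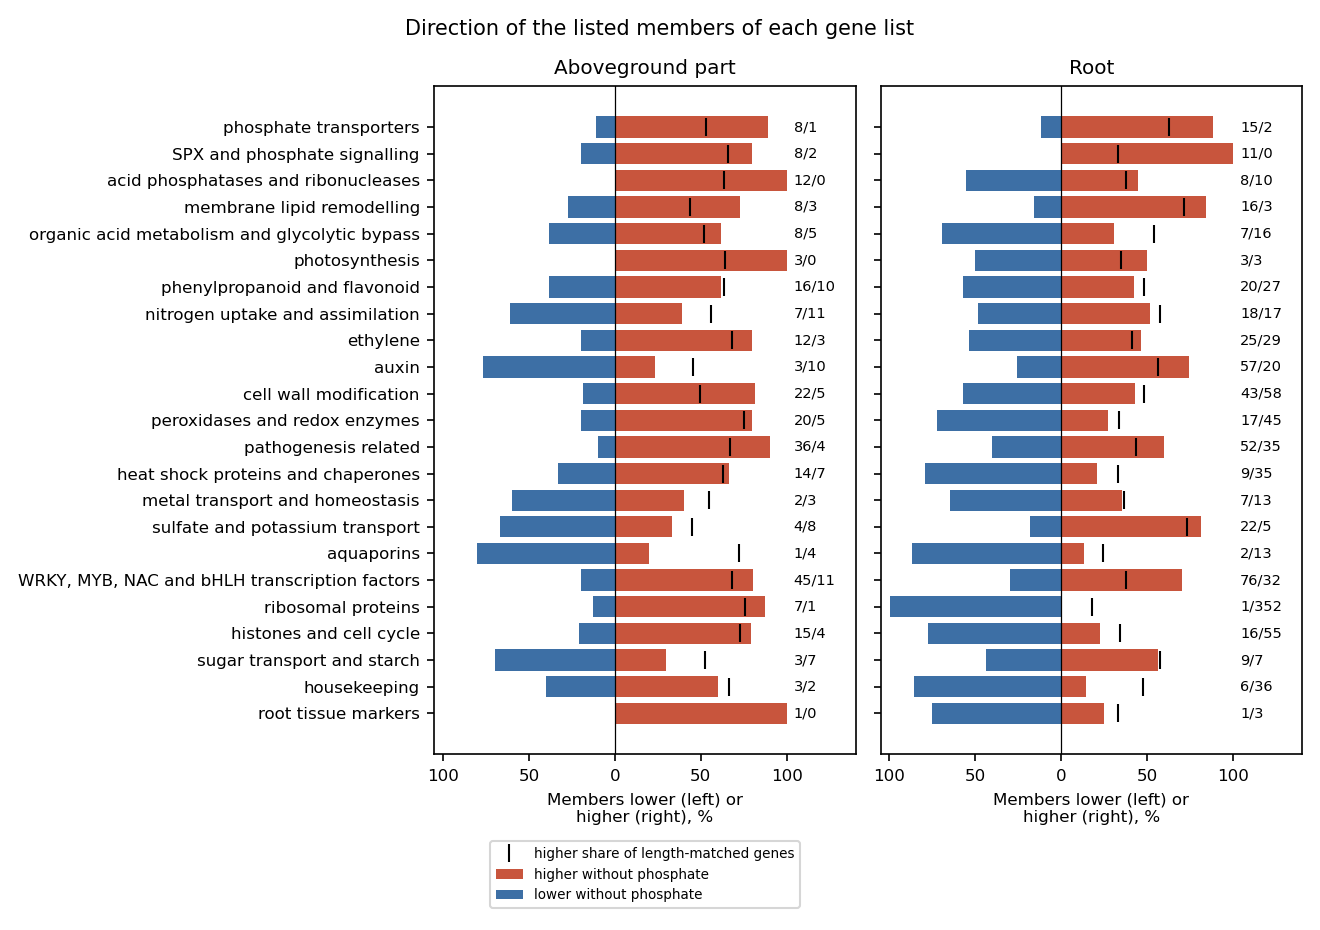
Share of the listed members of each of the 23 gene lists that were higher (right) or lower (left) in the library without phosphate, in percent, by tissue, with the counts higher/lower at the right of each panel. Vertical ticks mark the mean higher share of length-matched random lists. In the root 352 of 353 ribosomal protein genes were lower, while 8 of 9 aboveground and 15 of 17 root members of the phosphate transporter list were higher on the authors' scale.

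Ribosomal proteins had a median log2 ratio of -2.39 in the root, below all 10000 random lists of either matching, and -0.57 after the housekeeping shift. The length-matched lists had a median of -1.80. Ma02_g17870 (60S ribosomal protein L35-like) was 33.6-fold lower (17.5 to 74.3) and Ma10_g04060 (60S ribosomal protein L38-like) went from 51 counts to 1, 43.9-fold lower (7.53 to 1768). The 1 higher gene, Ma11_g05860, was named after its value was seen. Histone and cell cycle genes stood at 16 higher and 55 lower (median -2.17, and -0.36 after the shift). The histone Ma08_g06650 (histone H2AX-like) was 22.0-fold lower (5.77 to 186), while the kinase inhibitor Ma04_g33070 was 15.3-fold higher (9.62 to 25.9).

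Peroxidases and redox enzymes in the root stood at 17 higher and 45 lower (median -1.75, and 0.07 after the shift). The peroxidase Ma05_g15650 (peroxidase 44-like) went from 245 to 3 counts, 70.3-fold lower (23.8 to 343). Ma06_g16100 (peroxidase P7-like) went from 169 counts to none, in a group of 6 genes with the same description and length whose summed counts had a log2 ratio of -0.29. Cell wall modification genes stood at 43 higher and 58 lower (median -1.45, and 0.37 after the shift). Ma04_g21520 (expansin-B16-like), of a family that loosens growing walls, went from 109 counts to none, at least 31.3-fold lower (from 25.0), and the xyloglucan endotransglucosylase Ma01_g03800 was 85.0-fold lower (28.8 to 414). Of the aquaporins, which conduct water, 13 were lower and 2 higher (median -1.63, and 0.19 after the shift), with Ma08_g34320 (probable aquaporin PIP2-6) 19.2-fold lower (12.5 to 30.9). Heat shock proteins and chaperones (9 and 35, median -1.58), metal transport genes (7 and 13, median -1.24), ethylene genes (25 and 29, median -1.22) and phenylpropanoid genes (20 and 27, median -1.22) leaned lower, and each of these medians turned positive under the shift. Among length-matched random lists, the medians lay at percentiles 0.71 for peroxidases and redox enzymes, 0.04 for cell wall modification and 38.8 for aquaporins. They lay at 29.1 for heat shock proteins, 71.1 for metal transport, 53.4 for ethylene and 16.7 for phenylpropanoid genes.

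Auxin genes stood at 57 higher and 20 lower in the root (median 1.34, 3.16 after the shift, and -0.033 among members at 4-fold or more), although both named members were lower. Ma10_g20140 (auxin-induced protein 5NG4-like) went from 83 counts to none, at least 23.8-fold lower (from 18.9), and Ma05_g24620 (auxin-induced protein X10A-like) from 50 to 1, 43.1-fold lower (7.38 to 1734). WRKY, MYB, NAC and bHLH transcription factors stood at 76 higher and 32 lower (median 1.20), sulfate and potassium transport genes at 22 and 5 (median 1.57) and pathogenesis related genes at 52 and 35 (median 1.17), with 3.01, 3.39 and 2.99 after the shift. Among members at 4-fold or more the medians of the transcription factors (-2.01) and the pathogenesis related genes (-2.09) were negative, as was the mean of the latter over all members (-0.0041). That mean includes 3 genes with no count in 1 library, whose log2 ratios have no fixed size. The sulfate transporter Ma10_g27220 was 19.7-fold higher (14.0 to 28.8), and Ma02_g12840 (defensin Tk-AMP-D2-like) 81.2-fold lower (41.0 to 189). Nitrogen genes stood at 18 higher and 17 lower (median 1.26, 3.08 after the shift, and -1.26 with at least 50 counts). The peptide and nitrate family gene Ma11_g21310 had no count with phosphate and 108 without, at least 41.8-fold higher (from 33.4), and the nitrate transporter Ma01_g16930 was 16.5-fold lower (11.4 to 24.9). Sugar transport and starch genes (9 and 7, median 1.31, and 3.13 after the shift) and photosynthesis genes (3 and 3, median 0.21, and 2.02 after the shift) were divided. The lower photosynthesis members include Ma04_g34890, a ferredoxin--NADP reductase described as the root isozyme. The root tissue marker list was taken by words in the descriptions, and its members were not checked to mark roots. Of these, Ma03_g27060 (protein ROOT HAIR DEFECTIVE 3-like) was higher and 3 were lower. The 3 lower ones, named after their values were seen, were CASP-like genes: Ma06_g35350 had 20 counts with phosphate and 2 without, and Ma04_g08320 and Ma01_g08210 had 22 and 41 with phosphate and none without.

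The housekeeping list itself, of tubulins, actins and similar genes, was lower in the root, with 6 higher and 36 lower members (median -1.82), and 5 of the higher ones are chromatin regulators taken by the pattern. Ma05_g12090 (tubulin beta-7 chain-like) was 14.2-fold lower (11.4 to 17.6). With log2 ratios shifted by that median, 78.1% of the listed genes still past 2-fold were higher, in place of 44.5% on the authors' scale. No unlisted gene can enter, so this shift takes out lower genes only, and the share rises by construction.

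The direction of the listed genes went with gene length, in opposite ways in the 2 tissues. Aboveground, 77.7% of genes of up to 1000 bases and 21.7% of genes over 2000 bases were higher. In the root these shares were 18.3% and 83.8%. The Spearman correlation of length and log2 ratio, across genes that are not independent replicates, was -0.33 aboveground and 0.48 in the root.

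**Figure D3:**
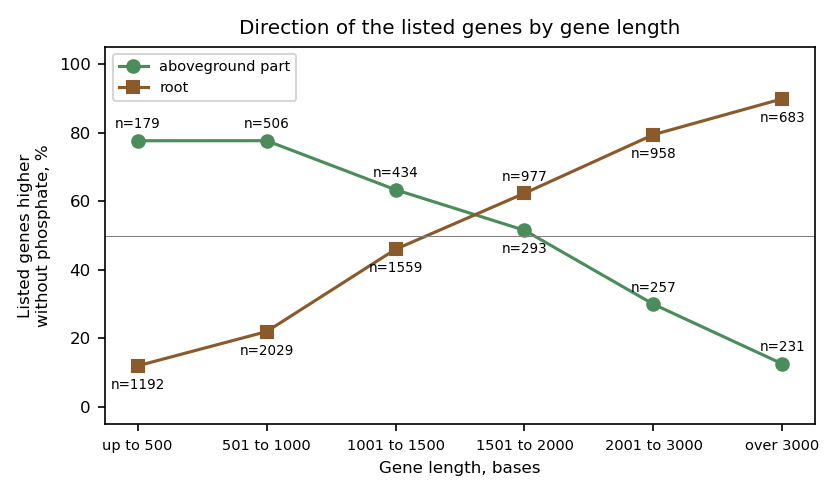
Percent of listed genes that were higher without phosphate by class of gene length in bases, in the aboveground part (circles) and the root (squares), with the number of genes in each class. The share goes from 77.7% to 12.6% with length aboveground and from 12% to 89.9% in the root.

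The comparison across tissues asked which genes were listed in both. There were 748 such genes, of which 280 were higher in both tissues and 76 lower in both. Another 112 were higher aboveground and lower in the root, and 280 were lower aboveground and higher in the root. The 356 genes of the same direction compare with 383 from the shares of higher genes among these 748 in each tissue alone. Of the 35 shared genes in the 4 phosphate response lists, 31 had the same direction, 30 of them higher in both, where their shares of higher genes alone give 29.5 and 29.3. Among the 122 genes at 4-fold or more in both tissues, 86 had the same direction, against 72.0 from their shares alone.

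The 3 genes that the rule took for the same direction across tissues were all higher in both. They were the transporter Ma03_g26260, Ma09_g06700 (disco-interacting protein 2 homolog C-like) and Ma02_g21730 (carotenoid 9,10(9',10')-cleavage dioxygenase 1-like). Other named genes, such as Ma10_g27220 and Ma04_g33070, were higher in both tissues too. Ma09_g06700 was 176-fold higher aboveground (88.9 to 408) and at least 112-fold higher in the root (from 90.7). Ma02_g21730 had no count with phosphate in either tissue and was at least 63.5-fold (from 51.1) and at least 30.6-fold higher (from 24.3). The 3 genes that the rule took for opposite direction were a lectin and a pair of dirigent proteins, which guide the coupling of lignans. Ma09_g10470 (mannose/glucose-specific lectin-like) was 15.7-fold higher aboveground (12.1 to 21.0) and 44.2-fold lower in the root (35.9 to 54.8). Ma10_g16880 (dirigent protein 21-like) was 24.1-fold higher aboveground (9.0 to 89.2) and 14.5-fold lower in the root (9.02 to 24.8), and Ma10_g16910 (dirigent protein 1-like) 13.1-fold higher (6.15 to 33.7) and 17.4-fold lower (13.0 to 23.5). With 1 library per group, none of these differences between tissues was tested.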

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

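The tests of scaling, and the share of family pairs expected from the length trend, were chosen after the results were seen. The other tests had their outcomes written down after a first look at length classes, list counts and the cross-table of tissues, but before the tested values were computed. For the family pairs the rule that reads the outcome was altered repeatedly after the share of 50.4% had been seen and was then put back as first written.

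The tissues differed in direction for 392 of the 748 genes listed in both, which drew attention because the same contrast went opposite ways. The difference of log2 ratios, root minus aboveground, was -9.44 for the lectin Ma09_g10470, -8.45 for the dirigent gene Ma10_g16880 and -7.82 for the dirigent gene Ma10_g16910. The median log2 ratios of 14 gene lists had opposite signs. Root minus aboveground, the medians differed by -4.41 for acid phosphatases and ribonucleases, -3.60 for ribosomal proteins, -3.51 for histones and cell cycle, -3.30 for cell wall modification, -3.27 for organic acid metabolism, -3.17 for ethylene and -3.15 for housekeeping genes. They differed by -2.94 for peroxidases and redox enzymes, -2.69 for heat shock proteins, -2.47 for phenylpropanoid genes, 2.42 for nitrogen genes, 2.51 for auxin, 2.55 for sugar transport and starch and 2.69 for sulfate and potassium transport. Under the housekeeping shift 5 of the 14 lists had medians of the same sign in both tissues, with differences of -1.26 for acid phosphatases and ribonucleases, -0.15 for cell wall modification, -0.016 for ethylene, -0.12 for organic acid metabolism and -0.45 for ribosomal proteins. The differences grew to 5.66 for auxin, 5.57 for nitrogen genes, 5.70 for sugar transport and starch and 5.85 for sulfate and potassium transport. They were -0.36 for histones and cell cycle, 0.47 for heat shock proteins, 0.21 for peroxidases and redox enzymes, 0.68 for phenylpropanoid genes and, by construction, 0 for housekeeping genes. None of these differences was tested. The aboveground shift hangs on 5 genes, 3 higher and 2 lower. No listed gene lies between a log2 ratio of -1 and 1, so medians of evenly divided lists jump by 2 or more.

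With all genes of the fixed lists left out, the root shares of higher genes still differed by 65.2 percentage points between genes over 2000 and up to 1000 bases. This argues against the short families of those lists as the whole cause, with 2518 short genes left. Other short families, such as mitochondrial electron transport (52 of 52 lower in the root), were not left out as such. The authors' length normalization was not tested, since length cancels in a ratio of FPKM. Had length alone set the ratio, the longest gene of a family should have been higher than the shortest in most families. It was so in 117 of 232 root families, 50.4% (95% exact interval 43.8 to 57.0). For pairs drawn independently, the trend across genes gives 63.2% (56.9 to 69.0). Aboveground, where long genes are the lower ones, it was so in 15 of 38 families, 39.5%, where the trend gives 41.5% (26.3 to 57.9), which leaves length open there. The opposite calls followed the trends: 80.4% of genes lower aboveground and higher in the root were over 1500 bases, and 89.3% of the reverse were up to 1500 bases, so the opposite calls may be largely those 2 trends seen again. What makes the trends stays open. The family pairs argue in the root against a ratio set by the listed gene length alone. Real families can share a direction, as the root ribosomal proteins did (352 of 353 lower), which the independent draws leave out. A length effect beside such shared directions therefore stays open. The pairs also cannot speak on a loss of RNA by its own length, since the listed length need not be that of the RNA. The phosphate treatment and other differences between single libraries were not tested.

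The lower ribosomal protein genes of the root are short, with a median of 468 bases. Their median lay at percentile 0 of length-matched random lists, below all draws, which argues against the length trend as the whole cause. The length-matched lists themselves had a median of -1.80 against -2.39, so genes of this length shared much of the difference. Scaling stays open: under the housekeeping shift the median went from -2.39 to -0.57 (95% interval of the median -0.64 to -0.47). That interval takes the shift as exact and the genes as independent, while the root housekeeping median has its own interval of -2.04 to -1.52. The shift comes from genes listed for passing 2-fold, so it cannot measure an error of scaling. Fewer dividing cells or slower growth without phosphate is a possible explanation that these libraries do not test, and any other difference between 2 single libraries stays open.

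The 4 phosphate response lists, taken as 1 list, were mostly higher in both tissues, but the root acid phosphatases and ribonucleases were not (8 higher, 10 lower, median -1.16, percentile 67.8 of length-matched lists), and root lipid remodelling lay at percentile 83.5. As 1 list they had 36 higher and 6 lower members aboveground (median 3.37) and 50 and 15 in the root (median 1.77), at percentile 100 of length-matched lists in both, which argues against the length trend as the whole cause. Under the housekeeping shift the medians were 2.04 aboveground (95% interval of the median 0.95 to 2.58) and 3.59 in the root. That interval takes the shift as exact and the genes as independent, while the aboveground housekeeping median has its own interval of -2.25 to 1.58. The shift comes from genes listed for passing 2-fold and cannot measure an error of scaling, which stays open. A response to withheld phosphate is consistent with these values as a hypothesis, found and examined on the same 4 libraries with no replicate.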

How the results depend on the processing

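The restriction to genes of 1000 to 2000 bases, the lists without off-name members and the length-matched lists were chosen after seeing the data; all other alternatives were planned. Within a tissue no paired analysis was possible, because each group is 1 library, and the results come from no test. A fit with tissue as the block, which the 4 libraries would allow for the 748 shared genes, was not made. Counts of listed genes moved by their own construction. A log2 ratio of at least 2 left 581 aboveground genes (394 higher, 187 lower), 2858 root genes (947, 1911) and 122 in both tissues (86 of the same direction, 36 opposite). An FDR of at most 1e-10 left 864 (525, 339), 3967 (1823, 2144) and 328 (170, 158). Counting intervals beyond 2-fold left 984 (634, 350), 4762 with 1992 higher, and 301 (187, 114). Genes of 1000 to 2000 bases left 727 (426, 301), 2536 (1326, 1210) and 237 (159, 78), where the shares of higher genes alone give 137 of the same direction. The housekeeping shift left 1128 aboveground with 292 higher, 4215 in the root with 925 lower, and 411 in both with 123 of the same direction; it can only take genes out of the tables, since genes that were not listed cannot enter. That shift rests on 5 aboveground genes with log2 ratios from -2.25 to 1.58. It turned the sign of 5 of 22 list medians aboveground and 9 of 23 in the root. A minimum of 50 counts and a pseudocount of 1 kept every such count within 1.5 times. Of the recomputed list medians 180 stayed within their interval with the same sign, 33 moved outside it without a change of sign and 16 reversed. Some reversed values still lay within an interval that held both signs, such as root nitrogen genes (-1.26, within -1.62 to 2.03). With members at a log2 ratio of at least 2 the aboveground medians reversed to -2.05 for phenylpropanoid genes, 2.90 for auxin, 2.61 for metal transport, 2.17 for sulfate and potassium transport and -2.25 for housekeeping. The auxin, metal transport and housekeeping values here are each 1 gene. In the root the medians reversed to 2.41 for acid phosphatases, 0.16 for organic acid metabolism, -0.033 for auxin, -2.09 for pathogenesis related genes, -2.01 for transcription factors and -0.79 for sugar transport and starch. A minimum of 50 counts reversed root photosynthesis (-1.70), nitrogen (-1.26) and root tissue markers (1.08), of which only Ma03_g27060 was left. The photosynthesis value is that of Ma04_g34890, a ferredoxin--NADP reductase described as the root isozyme. The mean in place of the median reversed root pathogenesis related genes (-0.0041) and sugar transport and starch (-0.50). Both means include genes with no count in 1 library, whose log2 ratios have no fixed size. The cause of the reversals was not tested beyond the absence of listed genes near 0. The root medians at a log2 ratio of at least 2 moved to 4.00 for phosphate transporters, 2.67 for lipid remodelling and -2.74 for ribosomal proteins, and the aboveground mean of acid phosphatases was 4.02. That mean also includes a gene with no count with phosphate. Under a pseudocount and under scaling to the tables' own totals no named gene changed sign; 42 of these ratios moved outside their counting interval and 174 did not. Depth limits most the genes with 0 to 3 counts in 1 library, whose intervals are the widest.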

Other observations

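The 18 gene groups looked at here, and their comparison with random lists, were chosen after the tables had been seen.

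The 4 lectins listed aboveground (median log2 ratio 2.62, and 1.28 under the housekeeping shift) lay at percentiles 93.7 and 94.1 of random lists matched on expression and on length, and the 8 in the root (-5.16 and -3.35) below all random lists of either kind. A cluster of 4 mannose/glucose-specific lectin-like genes, numbered next to each other, took 438 fragments aboveground with phosphate and 2986 without, but 20031 and 333 in the root, 0.440% and 0.00849% of all root fragments. All 4 soluble inorganic pyrophosphatases listed aboveground were higher (median 4.43, and 3.10 under the shift), while in the root 4 were higher and 6 lower (median -1.26, and 0.55 under the shift), at percentiles 55.3 and 84.3. These 10 include a pair of the same description and length with opposite calls, whose summed counts had a log2 ratio of 2.92. The pyrophosphatase gene Ma10_g00360 went from 165 to 12576 counts aboveground, 75.6-fold higher (95% counting interval 64.9 to 88.7), and was 47.7-fold higher in the root (33.8 to 69.6).

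Several families had all their listed root genes lower. These were 25 tubulins (median -2.02, and -0.20 under the housekeeping shift), 11 expansins (-3.57 and -1.75) and 18 arabinogalactan proteins (-2.55 and -0.74), whose medians lay at percentiles 0.04, 0 and 0.43 of length-matched lists. Tubulins are part of the housekeeping list that sets the shift, so their shifted median is near 0 partly by construction. The 52 genes of mitochondrial electron transport (-2.24 and -0.43), 32 proteasome subunits (-1.51 and 0.31) and 12 V-type proton ATPase subunits (-2.24 and -0.43) were lower too, at percentiles 11.0, 50.4 and 13.2. The median length of the root kinesins was 3026 bases and 29 of 30 were lower (median -1.83, and -0.0078 under the shift), where length-matched lists had a mean of 25.7 of 30 higher. The 8 kinesins listed aboveground were all lower (median -2.57, and -3.90 under the shift), at percentile 0 of length-matched lists. In the root 173 of 224 receptor-like kinases and 32 of 37 ABC transporters were higher, against 164 and 28.4 in length-matched lists.

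Pairs or groups of genes with the same description and length but opposite calls numbered 2 aboveground and 14 in the root. Reads shared between such copies can be divided differently in each library. The log2 ratio of the summed counts lay within 1 of 0 in 1 of the 2 aboveground groups and 9 of the 14 root groups, while the summed counts of the aquaporin TIP2-2 pair Ma09_g29530 and Ma06_g07460 aboveground kept a log2 ratio of 2.23.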
